A study of Homo sapiens with 16 samples.

How the data were processed

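The samples were 4 human cancer cell lines (HGC27, AGS, CCK81 and SW948), each treated with RHOA siRNA or a negative control RNA, with 2 arrays for each of the 8 groups and 16 arrays in all. Per the labels the lines were grown in 2D and the cells were moved to ultra-low-attachment plates after the knockdown, total RNA was isolated on columns, and cRNA was labelled with Cy3 for 1-colour hybridisation. The series text says that the experiments were done 2 times and does not say further whether the replicates were separate cultures, so the p-values measure the spread between these samples only.

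The arrays were scanned and read by the authors with Agilent Feature Extraction 11.5.1.1. Per the file headers, gProcessedSignal is an intensity from which background was subtracted and spatial trends were removed within each array, with a surrogate value for spots not above background. Per the file headers, gMeanSignal and gBGMedianSignal are the raw intensity of the spot and of its local background. Per the file headers, columns such as gIsWellAboveBG, gIsSaturated and gIsFeatNonUnifOL hold flags of 0 or 1 for each spot. Probe coordinates in the files are on hg19. The deposited value table is in log2 units: each of its columns correlated at 0.999986 or more with the log2 intensity of its own array over 58163 probes, had its 75th percentile at 0, and showed no centring by gene, and the authors do not state the steps. No column of the table was left without an array.

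An array held 62976 spots, of which 2075 were control spots, and the rest read 58201 probes. Of these probes 9293 carried no gene name, and the other 48908 carried 34757 gene names. Spots of the same probe were averaged, and 38 probes, with or without a name, were left out because every spot of theirs was an outlier on some array. Names were updated with a RefSeq gene table (assembly GRCh38.p14, used for names only): 22443 by accession, 927 by symbol and 231 by synonym, and 11156 kept the name in the file.

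The values used were log2 of gProcessedSignal minus the array's 75th percentile over noncontrol probes. A probe was tested when it was well above background on both arrays of at least 1 of the 8 groups, and the probe with the highest mean signal over all arrays stood for its gene. That left 22273 genes, of which 18086 are in the RefSeq table and 4987 have systematic or lnc names, and 3684 probes without a gene name, tested separately. No spot was saturated, and 44.6% to 51.8% of probes were well above background on an array. Signal near background limits the precision of folds, so where a gene was not well above background in 1 of the groups its fold is given as "at least", computed with values of the dim group raised to the lowest signal that was well above background on each array, and where it was above it in neither group no fold is given.

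A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 1.86 prior degrees of freedom), with no covariates. The contrasts were siRHOA minus control in each line, their mean over the 4 lines, the difference of AGS, CCK81, SW948 and the mean of these 3 mutant lines from HGC27, and a moderated F test for any difference among lines. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a contrast. All tests were two-sided.

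Gene lists, 24 of them with 624 genes of which 586 were tested, were written before the data were examined. Results are given for these: SRF/MRTF targets, YAP/TAZ targets, Wnt/beta-catenin targets, S phase, mitosis, p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, the unfolded protein and ATF4 response, cholesterol synthesis, hypoxia and glycolysis, ERK feedback targets, epithelial junctions, mesenchymal transition, focal adhesion, apoptosis and anoikis, TGF-beta and BMP targets, intestinal and gastric differentiation, leukocyte markers, and fibroblast and endothelial markers. The last 2 stand for other cell types that a culture could hold. Each list with at least 5 tested genes was tested in each contrast with camera (preset correlation between genes of 0.01), with camera at an estimated correlation and fry beside it, adjusted over the 24 lists. Camera compares a list with the other genes; fry tests whether its genes move one way on balance. Members were counted over all genes tested and adjusted over the list alone.

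The design, the gene lists, the alternatives and the rule for genes to be named were also fixed before the data were examined. Named genes were RHOA; in each line the 10 largest rises and falls among called genes whose siRHOA arrays both lay on the same side of both control arrays, leaving out names without a gene symbol; in the mean the 12 largest in each direction with the same sign in all lines; the 5 largest in each direction in each difference from HGC27; and up to 4 members of each list with the smallest adjusted p. The members of 3 of the lists are not reported. With 2 arrays against 2, chance alone sets all siRHOA arrays on the same side of both control arrays for 33.3% of genes. Genes called in a pair of lines were compared with the number expected from the product of their counts.

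The alternatives were normexp background correction (offset 50), quantile normalization, centring on the median, no filter and a strict filter on dim probes (well above background on all arrays), the mean of a gene's probes, the authors' value table, a replicate block, only the 4 arrays of a line, eBayes with a trend and a robust prior, array weights, a minimum change of 1 on the log2 scale, and leaving out each array in turn. Chosen after the data were seen were leaving out probes within 6 rows and columns of a control spot that came apart by more than 2 on the log2 scale, testing only genes above background in the line, and leaving out RHOA and lnc-DERA-1. Positions of spots were compared with 1000 random draws, with and without control spots, and treatment labels were regrouped within lines.

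The fit was tested on simulated data with 50 planted genes at each size. At a log2 change of 1, 52% of planted genes were recovered in a single line, HGC27. The share was 78% in the mean of the 4 lines and 26% in a difference between lines, SW948 minus HGC27. At a log2 change of 3 the shares were 98%, 100% and 82%. Genes called without a planted change numbered 9, 10 and 5. A planted list was called and no other list was. Noise was drawn independently for each gene, so the simulation could not show false list calls from genes that vary together. Each gene had 1 spread for all lines. The simulation therefore could not show false calls or lower recovery in a line whose replicates vary more, such as SW948. In the data the estimated correlation within a list reached 0.881 (cholesterol synthesis). Slides, 2 with 8 arrays each, hold HGC27 with CCK81 and AGS with SW948, so slide is inseparable from the line, and siRHOA arrays always lie in other columns of the slide than control arrays, so slide column is inseparable from the treatment. Per the file headers, CCK81 control replicate 1 carries another scan date than the other arrays of its slide. Tables were made with the R package data.table (version 1.17.8), and spot positions and figures with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.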

Results

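Gene expression was measured in 4 human cancer cell lines after RNA interference against RHOA, the small GTPase that controls actin stress fibres and contractility. Per the labels, HGC27 is a stomach cancer line with wild-type RHOA and AGS is a stomach cancer line with a heterozygous E64del change. The colon cancer line CCK81 carries R5Q and Y42C on different alleles, and the colon cancer line SW948 carries a heterozygous G17E change. Each line was treated with RHOA siRNA (siRHOA) or with a negative control RNA and then seeded on plates to which cells attach poorly. Each of the 8 groups held 2 arrays, 16 in all, so every value below rests on 2 arrays per group unless a larger number is given. The 75th percentile of signal ran from 67.1 intensity units (AGS siRHOA replicate 2) to 109 (HGC27 siRHOA replicate 2), and 44.6% to 51.8% of probes were well above background on an array. Replicates of a group correlated at 0.990 (SW948 control) to 0.995 (CCK81 control) across probes, which are not independent of each other. The small number of arrays limits the precision of every value. Signals are given as log2 with the array's 75th percentile at 0, changes as siRHOA minus control on the log2 scale with the standard error (SE), and probe positions on the hg19 build as the files give them.

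The first comparison asked how far the siRNA lowered its own target. RHOA fell in all 4 lines at its brighter probe (chromosome 3, 49397212 to 49397271). In HGC27 its signal went from 4.74 ± 0.03 (SD, n = 2) in control to 0.14 ± 0.03 (SD, n = 2), 24.2-fold lower, which left 4.13% of the control level (limma, adjusted p = 1.15e-06). In AGS it went from 5.69 ± 0.02 to 1.27 ± 0.28, 21.4-fold lower (adjusted p = 4.32e-06). In SW948 it went from 5.73 ± 0.02 to 1.38 ± 0.28, 20.4-fold lower (adjusted p = 2.16e-06). CCK81 kept the most RHOA, 14.6% of control: the signal went from 5.37 ± 0.01 to 2.60 ± 0.29, 6.83-fold lower (adjusted p = 0.00039). The difference between the CCK81 and HGC27 changes was 1.82 ± 0.24 (SE) and did not pass the test over all genes (adjusted p = 0.0682). A dimmer probe carrying the RHOA name (chromosome 3, 49449838 to 49449897), for which it was not known whether it lies in a RHOA exon, differed between the groups by 0.00 to 0.14. The mean of both probes gave RHOA changes of −2.30, −2.14, −1.38 and −2.16 in HGC27, AGS, CCK81 and SW948. With the 4 arrays of a line fitted alone, the fall passed the test in HGC27 and not in AGS, CCK81 or SW948 (adjusted p = 0.119, 0.355 and 0.146).

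**Figure D1:**
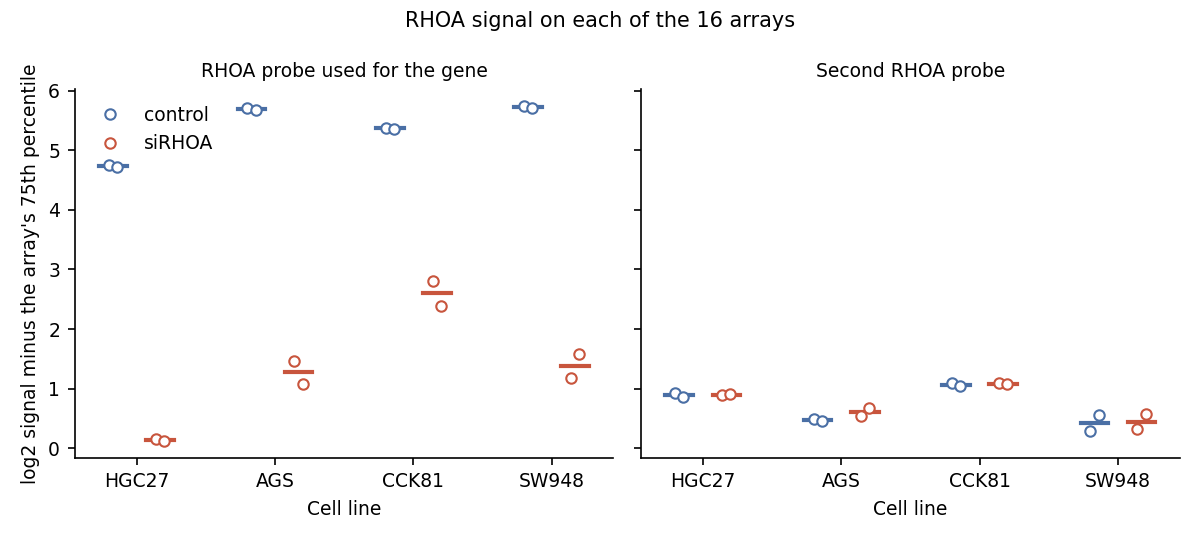
RHOA signal (log2, array 75th percentile at 0) on each array (points) with the group mean (bars), for control and siRHOA in each line, at the probe used (left) and at the second probe (right). At the probe used, siRHOA arrays of HGC27, AGS and SW948 average 0.14 to 1.38 and those of CCK81 average 2.60, against 4.74 to 5.73 in control, while the second probe shows almost no difference.

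In HGC27, the line with wild-type RHOA, the comparison asked what changes when normal RHOA is lowered. SLC36A1, an amino acid transporter of lysosomes and the plasma membrane, rose 2.31-fold (1.21 ± 0.13, n = 2 against 2, adjusted p = 0.00498), and SLC4A4, a sodium bicarbonate cotransporter, rose 2.29-fold (1.19 ± 0.12, adjusted p = 0.00492). The palmitoyltransferases ZDHHC14 and ZDHHC20 rose 2.29-fold and 2.13-fold, with another probe of ZDHHC20 at 0.10. SWAP70, an actin-binding protein that acts on Rac signalling, rose 2.19-fold (1.13 ± 0.13, adjusted p = 0.00965). RSPO2, a secreted enhancer of Wnt signalling, rose 2.09-fold (adjusted p = 0.0393). Among the falls, LPP, a LIM protein of focal adhesions, fell 2.21-fold (−1.14 ± 0.13, adjusted p = 0.00985), TRIAP1, an inhibitor of apoptosis, fell 2.09-fold (−1.06 ± 0.10, adjusted p = 0.00189), and PSMA4, a subunit of the proteasome, fell 1.88-fold (−0.91 ± 0.11, adjusted p = 0.01).

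Of 22273 genes tested, limma called 77 in HGC27, 37 higher and 40 lower with siRHOA, and 28 of them, 15 higher and 13 lower, changed by 1 or more on the log2 scale. EPCAM, an adhesion molecule of epithelial cells, and LONRF2, a ubiquitin ligase, were dim with siRHOA and fell at least 1.68-fold and at least 1.7-fold. The ribosomal RNA gene RNA5-8SN5 fell 2.33-fold (adjusted p = 0.0492) and C8orf44 fell by 0.88 on the log2 scale (adjusted p = 0.0355). The largest named rise was SHROOM2, a protein that binds actin at apical junctions (chromosome X, 9916998 to 9917057), which rose at least 5.52-fold from a dim control (4.49 ± 0.35, adjusted p = 0.000628); its probe lies within 6 spots of a control spot that also came apart in HGC27. ELOVL5, ZNF22-AS1 and FZD8 were called higher and TM4SF1 and AGT lower with each probe not well above background in either group, so no fold is given. TM4SF1 was at −1.26 at that probe and at 1.06 at another, and AGT turned from −1.13 to 0.076 with the authors' value table. Counts for HGC27 were 149 with normexp background correction, 381 with array weights, 29 with a replicate block and 1 with only the 4 HGC27 arrays. Among 23 called genes with several tested probes the probes of 8 disagreed in sign.

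Among the 24 gene lists, none moved together in HGC27 by camera or by fry in the main fit. Several other settings, given below, called 1 list, and a replicate block called 2. In the main fit the nearest was hypoxia and glycolysis, with a median of 0.10 over 27 genes and 23 of them positive (camera adjusted p = 0.059). In a test chosen after the data were seen this list also differed between the replicates of HGC27 (camera adjusted p = 8.91e-05, and adjusted p = 0.968 with an estimated correlation). In the epithelial junction list MARVELD2, the tricellulin of tight junctions, rose 1.52-fold (0.61 ± 0.08, adjusted p = 0.0222) and EPCAM fell, out of 30 tested members, and 3 rose and 2 fell when adjusted over the list alone. In the focal adhesion list LPP fell and the other 29 tested members did not pass, with 0 rising and 1 falling when adjusted over the list alone. SRF/MRTF targets, genes switched on by actin assembly, had a median of 0.00 over 31 genes, and YAP/TAZ targets, genes of the Hippo pathway, had a median of −0.03 over 30, with no member of either passing over all genes. When adjusted over the list alone 1 SRF/MRTF target rose and 1 fell, and 1 YAP/TAZ target fell.

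In AGS, with the E64del change, the comparison asked the same of a stomach line with mutant RHOA. SWAP70 rose 1.93-fold (0.95 ± 0.13, n = 2 against 2, adjusted p = 0.0264), SLC4A4 rose 1.77-fold (0.83 ± 0.12, adjusted p = 0.0402), and EPDR1, a secreted lysosomal protein, rose 1.73-fold (0.79 ± 0.12, adjusted p = 0.0493). KDR, a receptor for vascular endothelial growth factor (chromosome 4, 55945397 to 55945456), was dim in control and rose at least 2.11-fold (2.90 ± 0.18, adjusted p = 0.000141). APAF1, the scaffold that activates caspases in the apoptosome, fell 1.71-fold (−0.78 ± 0.10, adjusted p = 0.0145). Genes dim with siRHOA were B3GAT1, a glucuronyltransferase, which fell at least 1.82-fold (−2.78 ± 0.24, adjusted p = 0.00169), LGSN, which fell at least 1.11-fold (adjusted p = 0.00062), and ASS1, an enzyme of arginine synthesis above background on 1 control array, which fell at least 1.18-fold (adjusted p = 0.0111).

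Limma called 34 genes in AGS, 18 higher and 16 lower. For 16 of them the probe was above background on none of the 4 AGS arrays, and with only genes above background in AGS tested, a choice made after the data were seen, 12 genes were called. Among the named genes TDRKH, DNAH17, ART5, ARHGEF34P, GRM7-AS3 and S100Z were called higher, and XYLT1, LAPTM5, HSPA12B, APELA and ZNF536 lower, with the probe not well above background in either group, and LCNL1, called lower, was above it on 1 control array only. No list moved together by camera or fry, and the smallest camera adjusted p, 0.288, was shared by 4 lists, among them SRF/MRTF targets with a median of 0.12 and 23 of 31 genes positive. In the fibroblast and endothelial marker list KDR rose and the other 12 tested genes did not pass, and 2 rose when adjusted over the list alone. In the apoptosis and anoikis list APAF1 fell and the other 23 did not pass, with 0 rising and 1 falling when adjusted over the list alone. The AGS count was 86 without AGS siRHOA replicate 1, 80 with quantile normalization, 22 with normexp background correction, 17 with array weights, 10 with a replicate block and 0 with only the 4 AGS arrays. With normexp 4 of the 22 named genes called in AGS were still called. Among 6 called genes with several tested probes the probes of 4 disagreed in sign. ART5 was at 1.73 and −0.52, and APELA was at −0.92, 0.37, −0.18 and −0.18.

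In CCK81, with R5Q and Y42C, 5 genes were called. KLF2, a zinc finger transcription factor (chromosome 19, 16438246 to 16438305), rose 2.88-fold (1.53 ± 0.18, n = 2 against 2, adjusted p = 0.0392). CDK15, a cyclin-dependent kinase, was dim in control and rose at least 1.37-fold (2.58 ± 0.27, adjusted p = 0.0185). RHOA fell, and so did the long noncoding RNA lnc-DERA-1, named in CCK81 after its value was seen, by 5.25-fold (−2.39 ± 0.19, adjusted p = 0.00206), and NECAB2 was called lower (adjusted p = 0.0424) with its probe not well above background. By limma 2 were higher and 3 lower, while 924 genes had an unadjusted p under 0.05. KLF2 did not pass with normexp background correction (adjusted p = 0.0643) or with only the 4 CCK81 arrays (adjusted p = 0.355), and the count of genes was 49 without CCK81 control replicate 2, 133 with array weights and 2 without either AGS control array.

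By camera, 3 lists moved in CCK81. Of the 3, 0 were still called with the strict filter, with the mean of a gene's probes or by fry, and 1 with normexp background correction. Gastric differentiation genes shifted up with a median of 0.15 and 12 of 14 positive (adjusted p = 0.027, and adjusted p = 0.241 with an estimated correlation); no member passed over all genes and 2 rose when adjusted over the list alone, SOX2 and PGA3, each with a probe not well above background. Intestinal differentiation genes shifted up with a median of 0.15 and 20 of 25 positive (adjusted p = 0.0452, and adjusted p = 0.632 with an estimated correlation), with CDH17, an adhesion protein of gut epithelium, at 0.39 and no member passing either way. YAP/TAZ targets shifted down with a median of −0.08 (adjusted p = 0.027, and adjusted p = 0.632 with an estimated correlation); no member passed over all genes, and FJX1 at −0.94 and AMOTL2 at −0.55 fell when adjusted over the list alone.

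In SW948, with the G17E change, 773 genes were called, the most of the 4 lines when all arrays count equally. TAGLN, the actin-binding protein transgelin (chromosome 11, 117075155 to 117075214), rose 15-fold (3.91 ± 0.21, n = 2 against 2, adjusted p = 1.16e-05), LIMS2, an adaptor of integrin adhesions, rose 15.5-fold (3.95 ± 0.33, adjusted p = 0.000362), and KRT6A, a keratin of stratified epithelium, rose 18.7-fold (4.23 ± 0.50, adjusted p = 0.00259). KRT34, a hair keratin, and MYL2, a myosin light chain of heart muscle, were dim in control and rose at least 12.3-fold and at least 14.8-fold. IGFL1, a secreted growth factor-like protein, rose 29.4-fold (4.88 ± 0.68, adjusted p = 0.00537). Among the falls, GNG2, a subunit of G proteins, fell 7.21-fold (−2.85 ± 0.44, adjusted p = 0.00821), FGG, a chain of fibrinogen, fell 6.84-fold (−2.77 ± 0.40, adjusted p = 0.00681), and CMKLR1, the chemerin receptor, was dim with siRHOA and fell at least 2.14-fold (−3.24 ± 0.13, adjusted p = 2.16e-06).

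Limma called 490 genes higher and 283 lower in SW948, of which 256 rises and 88 falls were of 1 or more on the log2 scale. WFDC21P rose 18.2-fold, and CST6, an inhibitor of cysteine proteases, rose by 3.98 ± 0.66 on the log2 scale (adjusted p = 0.0124), with no fold given since 1 of 2 control arrays (SD 1.84) was not above background. LAYN, a receptor for hyaluronan, and PXDN, a peroxidase that crosslinks collagen IV, were dim in control and rose at least 5.02-fold and at least 10.2-fold. The potassium channel gene KCNJ5 fell at least 1.97-fold, the phosphatase gene PTPRO at least 1.31-fold, and SNAP91 and GSTA5, each above background on 1 of 2 control arrays, at least 1.38-fold and at least 1.2-fold. GZMA, which encodes a granzyme, fell 5.20-fold (−2.38 ± 0.56, adjusted p = 0.0499) and ODAM fell 5.02-fold (−2.33 ± 0.52, adjusted p = 0.0409). The count in SW948 was 337 without siRHOA replicate 1 and 1297 without control replicate 1, no gene passed with only the 4 SW948 arrays (4019 had an unadjusted p under 0.05 in the fit of all 16), and setting both replicate 1 arrays of SW948 against both replicate 2 arrays called 846 genes. With array weights SW948 had 153 genes against 381 in HGC27 and 133 in CCK81, which turned the order of the lines. Of the genes called in SW948, 30 of the 73 named ones were still called. The value of CMKLR1 in SW948 turned to 0.35 (adjusted p = 0.945) with no filter on dim probes, where a different probe stood for the gene.

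**Figure D2:**
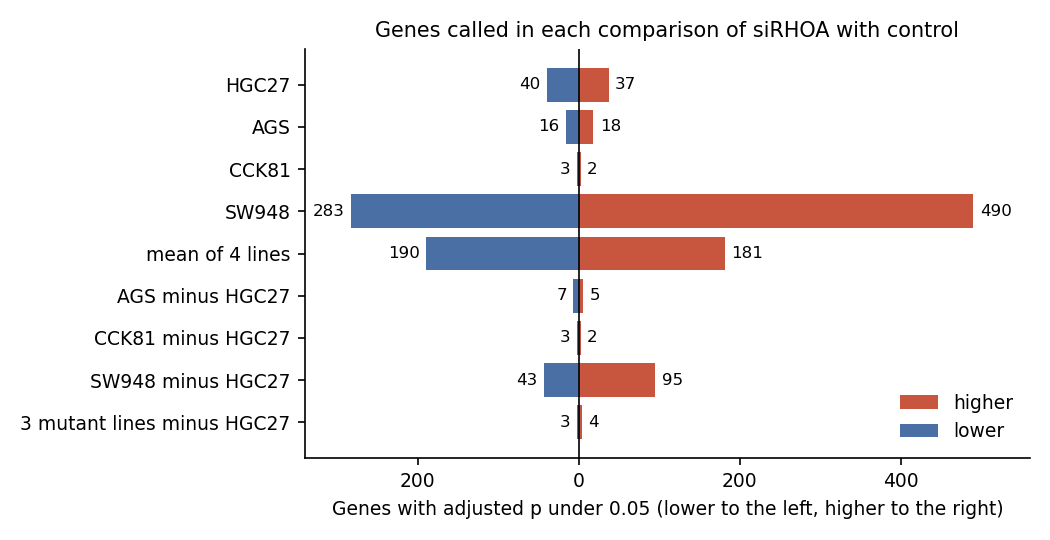
Number of genes called higher (right) and lower (left) with siRHOA, or higher and lower in the stated difference, in each of 9 comparisons, out of 22273 genes tested. SW948 stands at 490 higher and 283 lower, against 37 and 40 in HGC27, 18 and 16 in AGS and 2 and 3 in CCK81.

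Gene lists moved together in SW948, 11 of 24 by camera, and 6 of these also passed with an estimated correlation: SRF/MRTF targets, YAP/TAZ targets, ERK feedback targets, NF-kB and inflammatory cytokines, epithelial junctions, and TGF-beta and BMP targets. Of 31 SRF/MRTF targets tested, 7 rose and 0 fell over all genes, and 12 rose when adjusted over the list alone (median 0.26, 24 positive, camera adjusted p = 8.2e-08). Beside TAGLN, MYL9, a myosin light chain of smooth muscle, rose 5.78-fold (2.53 ± 0.27, adjusted p = 0.0014), FHL2, a LIM domain coactivator, rose 1.94-fold, and ZYX, the focal adhesion protein zyxin, rose 1.66-fold. Of 30 YAP/TAZ targets, 9 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (median 0.31, camera adjusted p = 1.46e-08). The matrix proteins CCN1 and CCN2 rose 5.49-fold (2.46 ± 0.13, adjusted p = 1.16e-05) and 5.09-fold (2.35 ± 0.18, adjusted p = 0.00022), GADD45B, a stress response gene, rose 4.56-fold, and AMOTL2, a junction protein that binds YAP, rose 2.22-fold (1.15 ± 0.12, adjusted p = 0.00159). The member that fell was STK38L, a kinase of the Hippo pathway, at −0.71 ± 0.15 (adjusted p = 0.0293), named after its value was seen.

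ERK feedback targets rose as a group in SW948: of 22 tested, 6 rose and 0 fell, and 11 rose when adjusted over the list alone (median 0.59, camera adjusted p = 4.57e-07). EPHA2, a receptor tyrosine kinase, rose 2.79-fold (1.48 ± 0.19, adjusted p = 0.00415), DUSP4, a phosphatase of ERK, rose 2.40-fold, MYEOV rose 3.06-fold, and CCND1, the cyclin of G1 phase, rose 1.62-fold. Of 25 NF-kB and cytokine genes, 1 rose, CXCL1, a neutrophil chemokine, by 2.65-fold (1.41 ± 0.19, adjusted p = 0.00446), and 4 rose when adjusted over the list alone (median 0.48, camera adjusted p = 3.61e-05). Of 30 epithelial junction genes, 3 rose, the keratins KRT8 2.62-fold (1.39 ± 0.21, adjusted p = 0.0085) and KRT18 1.61-fold and the tight junction scaffold TJP1 1.41-fold, and 9 rose when adjusted over the list alone (median 0.25, camera adjusted p = 3.75e-05). Of 20 TGF-beta and BMP targets, 4 rose over all genes and 4 when adjusted over the list alone (median 0.26, camera adjusted p = 0.000863). Of these, CCN2 and JUNB are also in the YAP/TAZ and SRF/MRTF lists. In it ID2, an inhibitor of differentiation factors, rose 2.07-fold (1.05 ± 0.20, adjusted p = 0.023), SMAD7, a brake on TGF-beta signalling, rose 1.97-fold, and JUNB, an AP-1 transcription factor, rose 1.6-fold, the last 2 at probes within 6 spots of a control spot that came apart.

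For 5 further lists in SW948 the camera call was lost with an estimated correlation. By fry, focal adhesion genes (adjusted p = 0.0123) and Wnt/beta-catenin targets (adjusted p = 0.0136) passed, and the other lists of the 5 did not. All of the 5 but the Wnt/beta-catenin list also shifted between the replicates of SW948 by camera, as given below. Of 30 focal adhesion genes 6 rose, with CAV1, the main protein of caveolae, at 11.3-fold (3.50 ± 0.34, adjusted p = 0.00092), LAMA3, a laminin chain, at 2.38-fold, ITGA1, a collagen-binding integrin, at 2.26-fold, and PXN, the adaptor paxillin, at 1.64-fold. When adjusted over the list alone 12 rose and 3 fell (median 0.21, camera adjusted p = 0.000304, and adjusted p = 0.231 with an estimated correlation). Of 27 hypoxia and glycolysis genes 3 rose both over all genes and when adjusted over the list alone (median 0.26, camera adjusted p = 0.000624, and adjusted p = 0.433 with an estimated correlation): ADM, a vasodilator peptide, 2.34-fold, ENO2, an enolase, 1.88-fold, and SLC2A1, a glucose transporter, 1.77-fold. Of 35 interferon-stimulated genes 1 rose, RSAD2, above background on 1 of 2 siRHOA arrays, at least 1.04-fold, and 7 rose and 1 fell when adjusted over the list alone (median 0.28, camera adjusted p = 0.000823, and adjusted p = 0.365 with an estimated correlation). Mitosis genes shifted down with a median of −0.17 and 6 of 35 positive, with no member passing either way (camera adjusted p = 0.021, and adjusted p = 0.771 with an estimated correlation). CENPA, a histone of the centromere, was at −0.38 (adjusted p = 0.24). Wnt/beta-catenin targets shifted down with a median of −0.30 and 4 of 24 positive (camera adjusted p = 0.0227, and adjusted p = 0.105 with an estimated correlation). In that list CCND1, which the ERK list also holds, rose over all genes, and 1 rose and 4 fell when adjusted over the list alone, with AXIN2, a feedback gene of the pathway, at −0.33 (adjusted p = 0.116) and the transcription factor gene SP5 at −0.63 (adjusted p = 0.0571).

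The following lists did not move as groups in SW948 by camera. Of 27 unfolded protein and ATF4 genes 4 rose over all genes and over the list alone (median 0.07, camera adjusted p = 0.11, and adjusted p = 0.048 by fry): PPP1R15A, a phosphatase subunit that restores translation, 2.52-fold (1.33 ± 0.13, adjusted p = 0.000734), ATF3, a stress transcription factor, 1.81-fold, SESN2 at 0.53 and CEBPB at 0.42. Of 25 intestinal differentiation genes 3 rose both ways (adjusted p = 0.519), KLF4, a transcription factor of gut epithelium, 2.32-fold, CA2, a carbonic anhydrase, 2.06-fold, and KRT20, a keratin of gut epithelium, 2.06-fold, although the list's median was −0.17 while its mean was 0.12. Of 26 p53 targets 3 rose, and 3 rose and 1 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.519), PLK2, a stress-responsive kinase, 2.49-fold, PMAIP1, which promotes apoptosis, at 0.59 ± 0.14, and SESN2, which the ATF4 list also holds. Of 24 apoptosis genes CASP10, an initiator caspase, rose 3.17-fold (1.67 ± 0.26, adjusted p = 0.01), and 3 rose and 1 fell when adjusted over the list alone (median 0.04, adjusted p = 0.519). No S phase gene of 33 passed (median −0.02, adjusted p = 0.992), no cholesterol synthesis gene of 25 (median 0.01, adjusted p = 0.967) and no mesenchymal transition gene of 21 (median 0.03, adjusted p = 0.519). No gastric differentiation gene of 14 passed over all genes and 1 rose over the list alone (median −0.06, adjusted p = 0.967). Markers of other cell types did not pass: 0 of 12 leukocyte markers (median 0.07, adjusted p = 0.519) and 0 of 13 fibroblast and endothelial markers (median 0.05, adjusted p = 0.203).

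**Figure D3:**
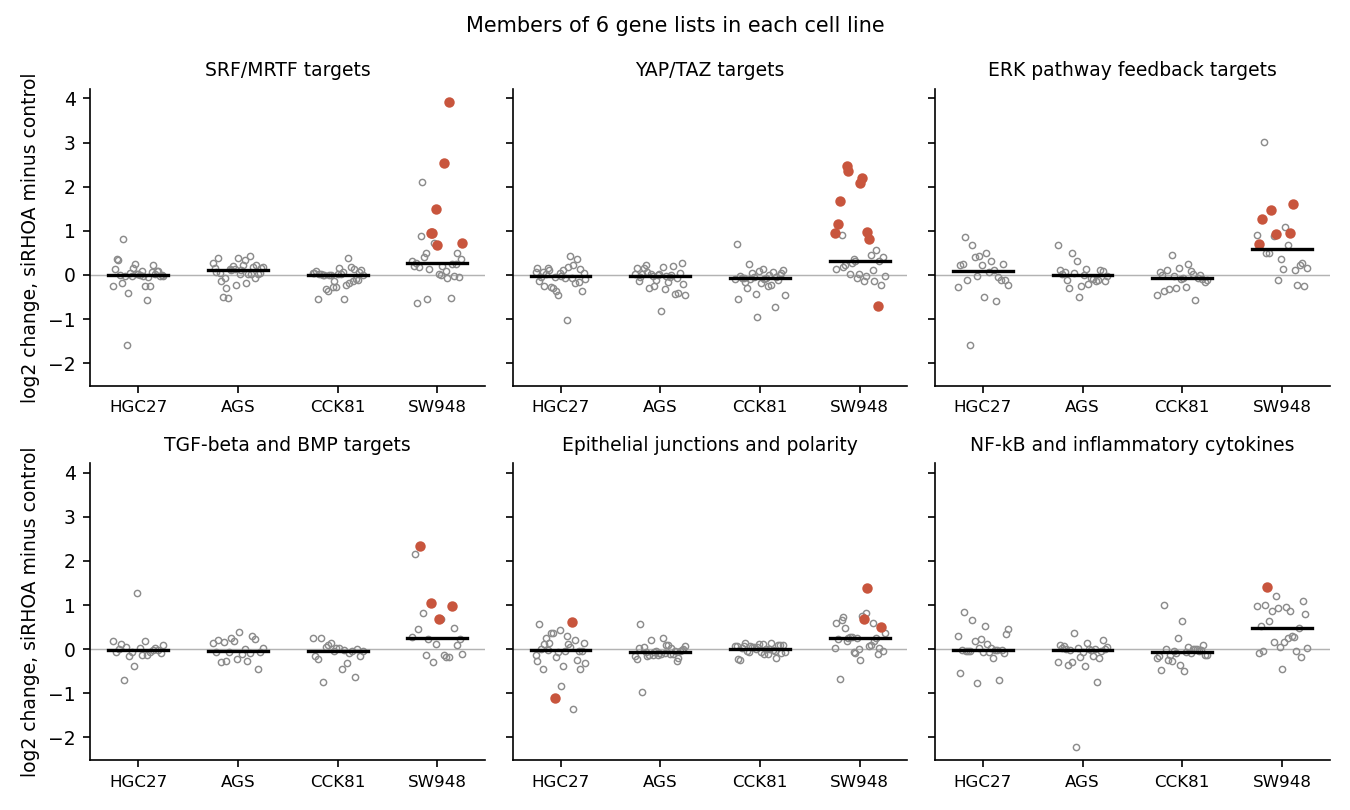
Change with siRHOA (log2) of each tested member of 6 gene lists (points) in each line, with members called at adjusted p under 0.05 in filled red and the list's median as a black bar. In SW948 the medians are 0.26 for SRF/MRTF targets, 0.31 for YAP/TAZ targets and 0.59 for ERK feedback targets, against 0.00, −0.03 and 0.09 in HGC27.

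The mean over the 4 lines asked which genes changed with siRHOA on average. With 1 knockdown reagent for all lines, a response to RHOA loss cannot be told apart from the siRNA acting on other transcripts. An effect of the slide column cannot be told apart from either. Its standard error rests on replicates within groups, so 1 line alone can carry a call. SWAP70 rose 2.06-fold (1.04 ± 0.06, 8 arrays against 8, adjusted p = 0.000148), with 1.13 in HGC27, 0.95 in AGS, 0.99 in CCK81 and 1.11 in SW948. SLC36A1 rose 1.95-fold (0.96 ± 0.06, adjusted p = 0.000148), ZDHHC20 rose 1.85-fold (0.89 ± 0.07, adjusted p = 0.000309), and CDK19, a kinase of the Mediator complex, rose 1.73-fold. Another probe of ZDHHC20 was at 0.10, 0.27, 0.19 and 0.85 in HGC27, AGS, CCK81 and SW948. SLC4A4 rose 1.67-fold in the mean but was at 0.05 in SW948, where it was not above background. EPHA2 rose 1.71-fold and PDGFB, a growth factor for mesenchymal cells, rose 1.67-fold, both most in SW948 (1.48 and 1.88). RHOA fell 16.4-fold (−4.03 ± 0.08, adjusted p = 1.19e-08) and lnc-DERA-1 (chromosome 12, 16573924 to 16573983) fell 7.26-fold (−2.86 ± 0.09, adjusted p = 4.74e-07), while its other probes were too dim to be tested and the labels name 1 knockdown reagent for all lines. TRIAP1 fell 1.67-fold (−0.74 ± 0.05, adjusted p = 0.000148) and PSMA4 fell 1.62-fold (−0.69 ± 0.05, adjusted p = 0.000309), each lower in all 4 lines.

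Limma called 371 genes in the mean of the 4 lines, 181 higher and 190 lower, and 292 of them had the same sign in every line. FGF20, a fibroblast growth factor, fell 2.05-fold (−1.04 ± 0.16, adjusted p = 0.0106). FGF20 was at −1.98 in CCK81 and −2.01 in SW948 against −0.01 in HGC27 and −0.15 in AGS, and another FGF20 probe was at −0.04 in CCK81. ST3GAL5, which makes the ganglioside GM3, fell 1.78-fold, and ADAMTS2, a procollagen protease, fell 2.00-fold, although another probe of ADAMTS2 did not show it. SHROOM2 at 1.30, CACNB4 at 0.76 and B3GAT1 at −0.75 were each carried by a single line, HGC27, SW948 and AGS. The noncoding transcripts LOC101928620, LOC100507336 and lnc-MRP63-6 rose by 1.26, 1.07 and 1.02, and lnc-TP53I13-2, XLOC_l2_010064, lnc-TUBA1C-2 and PEA15-AS1 fell by 0.94, 0.87, 0.77 and 0.71 on the log2 scale. PEA15-AS1 was at −1.73 in SW948. Counts for the mean were 787 with normexp background correction and 171 with no filter on dim probes.

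By camera, 4 lists shifted up in the mean of the 4 lines, none of them with an estimated correlation. With the strict filter on dim probes 1 of the 4 was still called. By fry SRF/MRTF targets alone of the 4 passed (adjusted p = 0.00288). Fry also called epithelial junctions (adjusted p = 0.00139) and TGF-beta and BMP targets (adjusted p = 0.0169), which camera did not. SRF/MRTF targets had a median of 0.12 with TAGLN rising (0.97 ± 0.10, adjusted p = 0.00197) among 31 tested, and 7 rose when adjusted over the list alone (camera adjusted p = 0.000348, and adjusted p = 0.295 with an estimated correlation). TAGLN was at 3.91 in SW948 and at −0.24, 0.42 and −0.19 in HGC27, AGS and CCK81. ERK feedback targets had a median of 0.16, with EPHA2 rising among 22 and 3 rising over the list alone (camera adjusted p = 0.0291, and adjusted p = 0.486 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.09, with the enolase ENO1 rising (0.44 ± 0.08, adjusted p = 0.0246) among 27 and 2 rising when adjusted over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.638 with an estimated correlation). Interferon-stimulated genes had a median of 0.10 with no member of 35 passing either way (camera adjusted p = 0.0274, and adjusted p = 0.541 with an estimated correlation). In the apoptosis list APAF1 fell (−0.36 ± 0.05, adjusted p = 0.00594), and 2 rose and 2 fell when adjusted over the list alone. In the YAP/TAZ list CCN1 (0.60 ± 0.06, adjusted p = 0.00212), CCN2 (0.61 ± 0.09, adjusted p = 0.0109) and GADD45B rose and STK38L fell. CCN1 and CCN2 were at 2.46 and 2.35 in SW948 and between −0.30 and 0.26 in the other lines. In that list 4 rose and 2 fell when adjusted over the list alone, and the list was not called as a group (camera adjusted p = 0.0777).

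Few genes were called in more than 1 line. RHOA and lnc-DERA-1 fell in all 4 lines and SWAP70 rose in HGC27, AGS and SW948, while 20 genes were called in 2 lines, 3 of them in opposite directions, and 838 in 1. HGC27 and SW948 shared 10 higher genes, among them SLC36A1, ZDHHC20, CDK19 and SWAP70, against 0.814 expected by chance, and 7 lower genes, among them TRIAP1 and PSMA4, against 0.508, and 2 genes went in opposite directions. Across genes, which are not independent replicates, the changes of a pair of lines correlated at r = 0.0239 (CCK81 and SW948) to r = 0.112 (HGC27 and AGS), and no pair shares control arrays. By Spearman's rank correlation the same pairs stood at 0.0665 and 0.209, again the lowest and the highest. Spread between replicates lowers such values, so they do not show that the lines respond unlike each other.

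The differences between lines asked whether lines with mutant RHOA respond unlike HGC27. TAGLN responded by 4.15 ± 0.29 more in SW948 than in HGC27 (n = 2 per group, adjusted p = 0.000159), KRT34 by 5.01 ± 0.65 more (adjusted p = 0.0128) and KRT6A by 4.71 ± 0.71 more (adjusted p = 0.0207). CMKLR1 responded by −3.23 ± 0.18 (adjusted p = 4.82e-05) and MC5R, a melanocortin receptor, by −2.81 ± 0.44 (adjusted p = 0.0248) relative to HGC27. In all 138 genes responded differently in SW948, 95 more positive and 43 more negative, with lnc-OR10H5-2 at 4.55 and LOC101928666 at 4.22 among the largest. This count rose with normexp background correction and fell with array weights, and that for AGS fell with normexp, as given below. AGS differed from HGC27 at 12 genes, KDR by 3.32 ± 0.25 (adjusted p = 0.00078), ART5 by 1.81 ± 0.24 and TM4SF1 by 1.25 on the positive side, and B3GAT1 by −2.68 ± 0.35 (adjusted p = 0.0386) and LAPTM5 by −1.70 on the negative. Of these genes TAGLN alone was above background in both groups of both lines. KRT34, KRT6A, CMKLR1, KDR, B3GAT1, TM4SF1, LAPTM5, lnc-OR10H5-2 and LOC101928666 were above it in neither group of HGC27, so the differences between lines stand as log2 values only. Another probe of ART5 was at −0.52 in AGS and −0.14 in HGC27, and another of TM4SF1 at −0.01 in AGS and 1.06 in HGC27, both against the stated direction. For CMKLR1 the SW948 difference turned to 0.92 (adjusted p = 0.859) with no filter on dim probes, where another probe stood for the gene.

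SHROOM2, lnc-CPSF7-1, lnc-AL020996.1-2, lnc-ANLN-4 and lnc-GLB1L2-1 made up all 5 genes that differed between CCK81 and HGC27, and 5 of 7 for the mean of the 3 mutant lines, 4 higher and 3 lower. In HGC27 itself these 5 changed by 4.49, −3.80, −3.32, 4.55 and 3.91, and the CCK81 difference was −4.36, 3.68, 3.25, −4.63 and −4.45. Each of their probes lies within 6 spots of a control spot that came apart on the HGC27 arrays. Without the probes that lie so, a choice made after the data were seen, 2 genes differed between AGS and HGC27, 0 between CCK81 and HGC27 (788 genes had an unadjusted p under 0.05 before), 112 between SW948 and HGC27 and 2 for the mutant mean. Of the 12 genes called before for AGS 5 had been left out, and of the 138 for SW948 7 had been. The other calls lost for these 2 lines were of genes that stayed in the test. The 2 genes called for the mutant mean away from such spots were TM4SF1 at 1.5 (adjusted p = 0.00149) and lnc-OR10H5-2 at 1.83 (adjusted p = 0.00394). The TM4SF1 value rests on a probe at −1.26 in HGC27, where another probe of TM4SF1 was at 1.06. The value of lnc-OR10H5-2 was at 4.22 in SW948 and at 0.28 and −0.01 in AGS and CCK81. HGC27 is the single line with wild-type RHOA, so RHOA status cannot be separated from the line. Any difference among the 4 lines was called for 112 genes (moderated F test in limma), and for 102 without those probes. Of 100 groupings of the treatment within lines, the real one among them, 7 called 112 or more, so chance was not excluded. These groupings cannot decide, because exchanging siRHOA and control in 1 line turns a response shared by the lines into a difference.

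**Figure D4:**
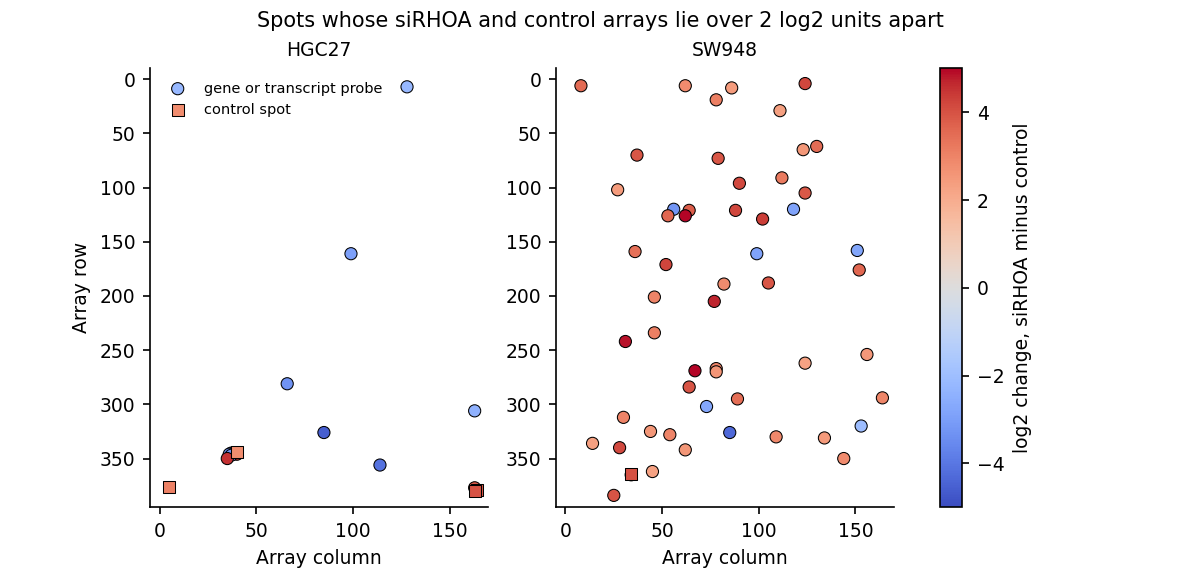
Row and column on the array of spots whose siRHOA and control arrays lie more than 2 apart (log2) in HGC27 (left) and SW948 (right), with colour for the change, circles for gene or transcript probes and squares for control spots. In HGC27, 10 of 17 such spots have another within 6 rows and columns, and 4 are control spots; in SW948 this holds for 8 of 56, and 1 is a control spot.

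Lists were also compared between lines, 144 comparisons over 6 pairs of lines. Of these 34 differed by camera, most of them between SW948 and another line: 11 against AGS, 9 against HGC27 and 9 against CCK81. None differed with an estimated correlation, where the smallest adjusted p, 0.0606, was shared by epithelial junctions in SW948 against each other line and by YAP/TAZ targets and TGF-beta and BMP targets in SW948 against CCK81.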

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

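The tests on array position, gene response, cross-hybridisation, another transcript, depth of knockdown, replicate spread and replicate number below were chosen only after the results were seen, while the other groupings of the SW948 arrays and of the treatment were planned.

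Responses to siRHOA differed from those in HGC27, by a test of the difference itself in limma, for 12 genes in AGS, 5 in CCK81, 138 in SW948 and 7 in the mean of the 3 mutant lines, and 112 genes differed among the 4 lines. For AGS the differences were 3.84 for lnc-CPSF7-1, 3.36 for lnc-AL020996.1-2, 3.32 for KDR, 1.81 for ART5, 1.25 for TM4SF1, −4.51 for lnc-ANLN-4, −4.46 for SHROOM2, −3.95 for lnc-GLB1L2-1, −2.68 for B3GAT1 and −1.70 for LAPTM5. For CCK81 they were 3.68 for lnc-CPSF7-1, 3.25 for lnc-AL020996.1-2, −4.63 for lnc-ANLN-4, −4.45 for lnc-GLB1L2-1 and −4.36 for SHROOM2. For SW948 they were 5.01 for KRT34, 4.71 for KRT6A, 4.55 for lnc-OR10H5-2, 4.22 for LOC101928666, 4.15 for TAGLN, −4.54 for lnc-ANLN-4, −3.96 for lnc-GLB1L2-1, −3.94 for SHROOM2, −3.23 for CMKLR1 and −2.81 for MC5R. For the mutant mean they were 3.78 for lnc-CPSF7-1, 3.27 for lnc-AL020996.1-2, 1.83 for lnc-OR10H5-2, 1.5 for TM4SF1, −4.56 for lnc-ANLN-4, −4.25 for SHROOM2 and −4.12 for lnc-GLB1L2-1. The shift of a gene list differed between a pair of lines in 34 of 144 tests by camera, and in 0 with an estimated correlation.

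In data that the comparisons of genes did not use, limma called 7 probes without a gene name in HGC27, 2 in AGS, 1 in CCK81 and 27 in SW948, of 3684 tested. Control spots, which read no human gene, came apart by more than 2 on the log2 scale between siRHOA and control arrays at 4 of 2075 spots in HGC27, 1 in AGS and 1 in SW948.

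In HGC27, SHROOM2, lnc-ANLN-4 and lnc-GLB1L2-1 went from dim to bright and lnc-CPSF7-1 and lnc-AL020996.1-2 from bright to dim, beside control spots that came apart too. A position effect on the HGC27 arrays may account for them: 10 of the 17 spots that came apart in HGC27 had such a neighbour, against at most 6 in 1000 random draws (permutation p = 0.001, the smallest that 1000 draws allow). With control spots left out, 6 of 13 spots had such a neighbour, against a mean of 0.401 and at most 6 in 1000 random draws (permutation p = 0.002). For these 6 spots, SHROOM2, lnc-ANLN-4, lnc-CPSF7-1 and lnc-AL020996.1-2 among them, this argues against a response of the genes to the knockdown. It does not exclude one, since the bound set for this test, more than any draw, was not passed. The spot of lnc-GLB1L2-1 is not among the 6. Other genes called in HGC27, such as SWAP70 and TRIAP1, lie away from these spots, and 66 of the 77 remained called without the probes near them. Of the 77, 5 were left out with those probes, and the other calls lost were of genes that stayed in the test. What happened at these positions stays open, since siRHOA arrays also lie in slide columns of their own.

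The fall of lnc-DERA-1 in all 4 lines, 5.25-fold to 9.5-fold, went with that of RHOA. Against RHOA RNA binding to the lnc-DERA-1 probe as the sole source of the fall stands the share of signal lost. The signal lost at lnc-DERA-1 was 9.22% of that lost at RHOA in CCK81 and 2.29% in AGS, 4.02 times apart. A fixed share was needed if binding was the sole source and both probes read in proportion to RNA. Such binding as part of the fall is not excluded. In control cells RHOA was 0.96 higher in AGS than in HGC27 while lnc-DERA-1 was −0.43 relative to HGC27. The siRNA acting on the lnc-DERA-1 transcript, and a response of lnc-DERA-1 to the loss of RHOA, cannot be told apart, because the labels name 1 knockdown reagent for all lines.

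In SW948 773 genes were called, against 77, 34 and 5 in HGC27, AGS and CCK81, but array weights turned this to 153, against 381, 17 and 133. Replicate spread was larger, not smaller, in SW948: its smaller replicate SD was 0.357, above the 0.328 that was the largest in other lines. The fit shares 1 spread per gene over all groups, so a smaller spread in SW948 would not set its count apart. Sharing on average understates the spread of SW948, which can raise its count, and array weights were lowest for its groups (0.447 and 0.537). With a block for the replicate number 682 of the 773 genes were still called (1553 called). That result cannot decide on the difference between replicate 1 and 2 arrays. This difference runs across the treatment, so the block leaves each log2 change as it was. The RHOA change in SW948 was 0.25 ± 0.24 (SE) above that in HGC27 and 0.07 ± 0.24 above that in AGS, both within 2 SE. A deeper knockdown in SW948 than in these 2 lines was therefore not measured, although the error does not exclude it. Relative to CCK81, where RHOA fell less, the SW948 change was −1.58 ± 0.24, so a deeper knockdown stays open for that pair. Spread between SW948 arrays as a whole stays open. The difference between the replicate numbers, which called 846 genes, cancels out of each log2 change and so does not by itself make these calls. With 4 arrays a single grouping is left to measure any other spread, and it called 7. That count cannot decide, because the treatment and replicate differences then lie within its groups and raise their spread. The G17E change, the colon origin and other properties of the line stay open too, since 1 line carries each combination.

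Regrouping siRHOA and control within lines used 100 of 648 groupings. For the mean of the 4 lines 1 of the 100, the real grouping, reached 371 genes, the smallest share that 100 groupings allow. Chance alone was therefore unlikely. The highest of the others called 142, with replicate 1 set against replicate 2 in SW948 and the other lines as they were. Treatment differences lie within the groups of such groupings, which can lower their counts. An effect of the slide column, inseparable from the treatment, was not covered. Chance could not be excluded for the mutant mean against HGC27, where the real grouping called 7 genes and the highest of the others 17, with 25 of 100 calling as many. It could not be excluded for differences among the 4 lines either, with 112 genes against 138 in the highest of the others and 7 of 100 calling as many. For both, the groupings cannot decide. Exchanging siRHOA and control in 1 line turns a response shared by the lines into a difference between them.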

How the results depend on the processing

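The tests without probes near odd control spots, with only genes above background in the line, and without RHOA and lnc-DERA-1 were chosen only after the results were seen. Results are given as the count of called genes unless stated, genes shared by lines are those called in the same direction in at least 2 lines (20), and for each change below the cause was not tested, except that a strict filter and fits of 4 arrays or single arrays less leave fewer genes or fewer degrees of freedom.

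The falls of RHOA kept their direction under every alternative run and passed in all 4 lines, except with only the 4 arrays of a line, where the changes stayed at −4.42 in AGS, −2.77 in CCK81 and −4.35 in SW948 with adjusted p = 0.119, 0.355 and 0.146, against at most 0.0301 in those lines under other alternatives that keep all arrays. Over leaving out each array, RHOA ran from −4.62 to −4.57 in HGC27, −4.62 to −4.22 in AGS, −2.98 to −2.57 in CCK81 and −4.55 to −4.15 in SW948. Where an array was left out, the lone array of its group is assumed to vary like the other groups.

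With normexp background correction, HGC27 had 149 genes (77 before), AGS 22 (34), SW948 1399 (773), the mean 787 (371), AGS minus HGC27 1 (12), CCK81 minus HGC27 1 (5), SW948 minus HGC27 349 (138), the mutant mean 18 (7), any difference 248 (112) and genes shared by lines 43 (20), and 1 list was called in HGC27 (0). AGS went from 18 higher and 16 lower to 7 and 15. With quantile normalization AGS had 80 (34 higher and 46 lower), CCK81 9, AGS minus HGC27 27, the mutant mean 13 and AGS 1 list. With median centring HGC27 had 1 list. With no filter HGC27 had 48, CCK81 19, the mean 171, AGS minus HGC27 7, CCK81 minus HGC27 3 and HGC27 1 list. In that setting CMKLR1 in SW948 turned from −3.24 to 0.35 (adjusted p = 0.945) and from −3.23 to 0.92 in SW948 minus HGC27 (adjusted p = 0.859), since a different probe stood for it. With the strict filter AGS had 21, CCK81 8, the mean 628, any difference 52, genes shared 32, and AGS minus HGC27, CCK81 minus HGC27 and the mutant mean had 0 each, and CCK81 had 0 lists (3 before). With the mean of a gene's probes HGC27 had 1 list and CCK81 0. With the authors' table AGT turned from −1.13 to 0.076 in HGC27.

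With only the 4 arrays of a line HGC27 had 1 gene, AGS, CCK81 and SW948 0 each, genes shared 0, HGC27 1 list and CCK81 6 lists. With trend and robust prior CCK81 had 12, the mean 615, the mutant mean 12, genes shared 42 and HGC27 1 list. With array weights HGC27 had 381, AGS 17, CCK81 133, SW948 153, CCK81 minus HGC27 18, SW948 minus HGC27 74, the mutant mean 25, any difference 70, genes shared 52 and HGC27 1 list. With a minimum change of 1 HGC27 had 28, AGS 22, SW948 344, the mean 14 and genes shared 8. Testing only genes above background in the line gave 12 in AGS. Without probes near odd control spots AGS minus HGC27 had 2, CCK81 minus HGC27 0 and the mutant mean 2. Without RHOA and lnc-DERA-1 lines shared 18 genes in the same direction. With an estimated correlation CCK81 had 0 lists, SW948 6 of 11 and the mean 0 of 4, and fry called 0 in CCK81.

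The replicate block, which pairs arrays of the same number within a line, was run although nothing in the labels says that the numbers pair the arrays. With the block HGC27 had 29 genes (21 shared with the 77), AGS 10 (9 shared), SW948 1553 (682 shared), the mean 582 (286 shared), AGS minus HGC27 3, SW948 minus HGC27 268 (95 shared), the mutant mean 3 and genes shared by lines 12, and 2 lists were called in HGC27, 2 in AGS and 6 in CCK81. As a hint of pairing, deviations of arrays with the same number correlated at 0.0828 in HGC27, 0.109 in AGS, 0.0393 in CCK81 and 0.383 in SW948. A block for the slide was not run because slides and lines coincide.

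Leaving out each array gave 34 to 81 genes in HGC27, with 50 without HGC27 siRHOA replicate 1, 43 without either AGS control array, 35 without either CCK81 control array and 34 without either CCK81 siRHOA array. AGS ran from 22 to 86, with 69 and 66 without AGS control replicates 1 and 2, 86 and 65 without AGS siRHOA replicates 1 and 2, and 22 without either HGC27 control or either CCK81 siRHOA array. CCK81 ran from 2 to 49, with 12 and 49 without CCK81 control replicates 1 and 2, 24 without CCK81 siRHOA replicate 1, 8 without either SW948 control array, 11 without either SW948 siRHOA array, 3 without any HGC27 or AGS siRHOA array and 2 without either AGS control array. SW948 ran from 337 without SW948 siRHOA replicate 1 to 1297 without SW948 control replicate 1. The mean ran from 178 to 598, with 598 without SW948 control replicate 1, 194 to 223 without an HGC27 array and 178 to 193 without a CCK81 array.

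AGS minus HGC27 ran from 7 to 32, with 19 to 32 without any AGS or HGC27 array and 7 without either CCK81 siRHOA array. CCK81 minus HGC27 ran from 5 to 23, with 10 to 23 without any HGC27 array, 19 without CCK81 control replicate 2 and 8 without CCK81 siRHOA replicate 1. SW948 minus HGC27 ran from 69 to 390, with 390 without SW948 control replicate 1, 270 without SW948 siRHOA replicate 2, 84 without HGC27 siRHOA replicate 1 and 69 to 82 without a CCK81 array. The mutant mean ran from 7 to 46, with 31 to 46 without an HGC27 array, 11 without AGS siRHOA replicate 1 or SW948 control replicate 2 and 17 without SW948 siRHOA replicate 2. Any difference ran from 62 to 226, with 226 without SW948 control replicate 1, 73 without SW948 siRHOA replicate 1 and 62 to 67 without CCK81 control replicate 1 or a CCK81 siRHOA array. Genes shared by lines ran from 12, without HGC27 control or siRHOA replicate 1, to 25.

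Lists called over the same settings ran from 0 to 1 in HGC27, 0 to 4 in AGS, 0 to 3 in CCK81, 10 to 11 in SW948 and 1 to 7 in the mean, with 7 without SW948 control replicate 1 or siRHOA replicate 2. Of the 11 lists of SW948, 8 were still called without SW948 siRHOA replicate 1, 9 without SW948 control replicate 2 and 10 without either of the other SW948 arrays. The median of S phase genes in AGS ran from −0.15 to 0.28 and that of mitosis genes from −0.15 to 0.29, both negative without AGS control replicate 2 or siRHOA replicate 1. The median of cholesterol synthesis genes ran from −0.46 to 0.43 in SW948, negative and called without SW948 control replicate 1 or siRHOA replicate 2, and from −0.12 to 0.12 in the mean. Of values for single genes, 6346 kept their direction and side of the threshold under the other alternatives, 421 were lost, 161 were gained and 3 turned, and with an array left out 9918 were kept, 655 lost and 83 gained. Signal over background limits which genes can be tested and which folds can be given. With normexp 11 of 22 named genes passed in HGC27, 4 of 22 in AGS and 65 of 73 in SW948.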

Other observations

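The gene families by symbol and the differences between replicates below were tested only after the results were seen, over 1140 family tests in the 4 lines and their mean, of which 12 were called by camera and 0 with an estimated correlation. In SW948 the genes whose symbols begin with KRT shifted up: 13 of 46 tested rose and 0 fell, among the 13 the antisense RNA KRT10-AS1 and the pseudogenes KRT16P2 and KRT8P12, with a median of 0.66 (camera adjusted p = 3.88e-13, and adjusted p = 0.994 with an estimated correlation). Beside KRT34 and KRT6A, the keratins KRT14 and KRT17 of basal epithelium rose by 1.98 and 1.97 and the hair keratins KRT36 and KRT86 by 2.84 and 1.46. The family's median was 0.27 with normexp, 0.64 with quantile normalization and 0.65 with median centring. Myosin light chains shifted up too, with MYL2, MYL9 and MYL6 (0.39 ± 0.09 SE) rising among 10 (camera adjusted p = 0.0351, and adjusted p = 0.994 with an estimated correlation). Symbols beginning with ANXA, mostly annexins, which bind membranes with calcium, shifted up with a median of 0.29 (camera adjusted p = 0.0478, and adjusted p = 0.994 with an estimated correlation), with 4 of 17 rising, ANXA2 (0.84), ANXA11 (0.76) and the pseudogenes ANXA2P1 and ANXA2P3, and ANXA13 falling (−0.81).

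Of 17 genes whose symbols begin with ALDH, most of them aldehyde dehydrogenases, 4 fell in SW948, ALDH1A1 (−1.46), ALDH3A1 (−0.85), ALDH3A2 (−0.74) and ALDH18A1 (−0.59), with a family median of −0.29 (camera adjusted p = 0.0368, and adjusted p = 0.994 with an estimated correlation). Of 13 genes whose symbols begin with AKR, the aldo-keto reductases, AKR1B10 fell in SW948 (−1.05 ± 0.23 SE), with a median of −0.76 (camera adjusted p = 0.0161, and adjusted p = 0.994 with an estimated correlation), while the same family shifted up in CCK81 with a median of 0.37 and no member passing (camera adjusted p = 0.0187, and adjusted p = 0.994 with an estimated correlation). Metallothioneins shifted down in CCK81 with a median of −0.27 and no member of 15 passing (camera adjusted p = 0.0161, and adjusted p = 0.994 with an estimated correlation). The other calls were KRT in the mean (median 0.19, and 0.10 with normexp; camera adjusted p = 5.75e-06), SNORA, small nucleolar RNAs, in HGC27 (0.13 and 0.08, adjusted p = 0.0142) and in the mean (0.10 and 0.05, adjusted p = 0.0478), CHMP in CCK81 (0.13 and 0.10, adjusted p = 0.0161) and KCNK in AGS (−0.20 and −0.04, adjusted p = 0.0196), each with adjusted p = 0.994 with an estimated correlation. The signs of these family medians were the same with normexp, quantile normalization and median centring, but with normexp they lay nearer 0: myosin light chains at 0.15 (0.28 before), ANXA at 0.17, ALDH at −0.12, AKR at −0.52 in SW948 and 0.23 in CCK81, and metallothioneins at −0.26.

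Replicates of the same line differed as well, with replicate 2 set against replicate 1 over both treatments. In SW948 limma called 846 genes on this axis, and cholesterol synthesis genes had a median of 0.74 (camera adjusted p = 1.5e-24, and adjusted p = 0.113 with an estimated correlation). On the same axis of SW948 hypoxia and glycolysis genes shifted up by camera (adjusted p = 0.000501), as did mitosis genes (adjusted p = 0.0381), while interferon-stimulated genes (adjusted p = 0.0013), focal adhesion genes (adjusted p = 0.0171) and p53 targets (adjusted p = 0.0381) shifted down, none with an estimated correlation (adjusted p = 0.698 or more). The first 4 of these 5 lists are among the 5 whose treatment call in SW948 was lost with an estimated correlation. In AGS it called 83 genes, with a median of −0.44 for mitosis genes (camera adjusted p = 6.31e-36, and adjusted p = 0.0622 with an estimated correlation) and −0.41 for S phase genes (camera adjusted p = 3.5e-34, and adjusted p = 0.0622 with an estimated correlation). Targets of p53 (adjusted p = 1.06e-06), interferon-stimulated genes and intestinal differentiation genes (both adjusted p = 0.0141) shifted up on this axis in AGS by camera, with adjusted p = 0.0661, 0.372 and 0.167 with an estimated correlation. In HGC27 limma called 16 genes, with a median of 0.10 for hypoxia and glycolysis genes (camera adjusted p = 8.91e-05) and −0.13 for S phase genes (camera adjusted p = 0.00334), both with adjusted p = 0.968 with an estimated correlation. In CCK81 it called 2 genes and no list moved.

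Over single arrays, 193 genes lay higher and 245 lower on both siRHOA arrays than on both control arrays in each of the 4 lines, where 17.2 were expected by chance in each direction.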
